A study of Mus musculus with 8 samples.

How the data were processed

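RNA was measured in 8 single follicles of C57BL/6 mouse ovaries, with 1 sequencing library per follicle. Per the labels, the follicles were preantral (PF) or small antral (SAF) and came either from transplanted female germline stem cells (FGSCs, here TF) or from wild type mice (WT). Follicles were separated with a needle and polyadenylated RNA was copied with the SMARTer Ultra Low Input kit. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.1 to GRCm38. The read counter, the annotation, the strand setting, the age of the mice and the transplant hosts are not given in the sources used here.

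The authors deposited 1 table for the TF libraries and 1 for the WT libraries. Per the file headers, each holds raw counts per gene and library; the values are whole numbers, without normalization. The authors' normalized columns are a signal, the mean of a group's counts after 1 scale factor per library, set within each table. The authors' log2 column is the log2 ratio of the SAF to the PF signal, set to a fixed limit where one of them is 0. The deposited FDR column is an adjusted p-value of the authors' comparison of SAF with PF, by a test that is not named in the sources used here. Of the genes, 22129 are listed for TF and 22138 for WT, of which 21997 are in both. The counts of these shared genes in all 8 libraries were analysed together; 132 genes listed only for TF and 141 listed only for WT were left out of the tests.

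Total counts ran from 7656108 to 9805287 per library. A count of 0 allows up to 3 counts, which is 0.301 to 0.394 CPM (library-scaled counts) depending on the library. Such floors, and 95% intervals given for ratios, cover counting error only, since reads without molecular identifiers are not independent molecules. CPM are normalised read counts scaled with TMM factors.

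Genes were kept by filterByExpr on the 4 groups (min.count 10, min.total.count 15), which left 17925 genes. Of these, 16611 had a RefSeq record for GRCm38, from which positions were taken. GC content and transcript length were those of the longest GENCODE transcript, found for 16402 genes. The main test was the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and 1 mean per group, which left 4 residual degrees of freedom. The contrasts were the source effect (TF over WT) in PF and in SAF, the stage effect (SAF over PF) in WT and in TF, and their interaction. The source effect over both stages came from an additive model of stage and source with 5 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. The biological coefficient of variation at the common dispersion was 0.303.

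Gene lists, 37 in all, were tested with camera (limma 3.58.1) on log2 CPM from voom, with 0.5 added to each count, at a preset correlation of 0.01, beside camera with an estimated correlation and the rotation test fry, all adjusted over the 222 tests of lists and contrasts. The lists held the oocyte, germline and pluripotency, meiosis, granulosa, cumulus and ovulatory genes, steroidogenesis, theca and interstitial cells, ovarian stroma and fibroblasts, smooth muscle and pericytes, endothelium, macrophages and immune cells, erythroid cells, ovarian surface epithelium and luteal cells. They also held the cell cycle, p53 and DNA damage, atresia and lysosome, immediate early and heat shock genes, the unfolded protein response, the interferon response, TGF-beta, Notch, Hippo, Wnt and PI3K signalling, gap junctions, basement membrane, cholesterol synthesis, glycolysis, hypoxia, oxidative phosphorylation, the mitochondrial genome, cytosolic ribosomal proteins, the antioxidant response, imprinted genes, DNA methylation and chromatin, and fetal and testis somatic genes. A member rose or fell (in a source effect, was higher or lower in TF) where its adjusted p over all genes passed the threshold; counts adjusted over the list alone stand beside these.

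Genes named in the text followed a rule. Per contrast these were up to 8 genes with the largest change in each direction among those past the threshold, with no overlap between the libraries of the groups compared and a mean of at least 10 CPM in the higher group, without predicted genes, ribosomal protein genes and pseudogenes. Up to 4 members per list with the smallest p were added, and a set of marker genes whatever their test. Not all of these are printed below, and the markers Inhba, Foxl2, Fst and Kitl are given no values. A fold against a group with no counts is given as a lower bound against a floor of 3 counts per library, and a fold against a group with 1 to 3 counts as a ratio with its counting interval.

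Alternatives were RLE factors, no low-count filter, a filter at 10 CPM, the DESeq2 Wald test (DESeq2 1.42.0), a fit of only the 4 libraries compared, the replicate number as a block, each library left out in turn, limma voom with sample quality weights, and a threshold of 0.1. Comparisons, tests, lists, the naming rule and these alternatives were fixed before the data were examined. A correction for GC content and transcript length, a restriction to protein-coding genes, the authors' scale factors and a crossed replicate block were added later, as were pseudocounts of 2 and 5 in the list tests and a fit of Rps18 summed with its pseudogene. A library left alone in its group was assumed to vary like the other groups. The test was tested on simulated data with the means and dispersions fitted here and 200 changed genes. At a 4-fold change it recovered 38% of changed genes in the PF source effect and 52% in the SAF source effect. It recovered 56% and 32% in the stage effects of WT and TF, 14% in the interaction and 70% over both stages. False calls were 5 of 63 in the PF source effect and 5 of 77 in SAF. They were 3 of 69 and 10 of 68 in the stage effects of WT and TF. In the interaction they were 0 of 24, and over both stages 7 of 104. All real contrasts but the PF source effect had more calls than this, so a larger unadjusted p sufficed there. The PF source effect had fewer (39 against 63), so it needed a smaller unadjusted p. The simulated recovery does not carry over to the real contrasts.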

Results

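The series compared preantral and small antral follicles, per the labels from transplanted female germline stem cells, with follicles of wild type mice. The study was titled for the restoration of ovarian function. The labels do not say which cells of a TF follicle derived from the transplant. Each of the 4 groups, PF-WT, PF-TF, SAF-WT and SAF-TF, had 2 libraries, and every mean below is over n = 2 with its SD. Total counts were 7656108 and 8908290 in PF-WT, 8616124 and 9292314 in PF-TF, 9805287 and 8933128 in SAF-WT, and 9182465 and 8439542 in SAF-TF. Between 18796 genes (PF-TF replicate 1) and 20694 genes (PF-WT replicate 2) had at least 1 count. Log2 CPM correlated at 0.945 to 0.972 between replicates, at 0.877 to 0.952 between sources at the same stage, and at 0.692 to 0.821 between stages of the same source, across genes, which are not independent replicates. The variance between replicate counts was 10.2 (SAF-WT) to 36.8 (PF-WT) times that of counting error, as chi-square per degree of freedom. The labels do not say whether the follicles of a group came from separate mice, so each p-value measures only the spread between these follicles.

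**Figure D1:**
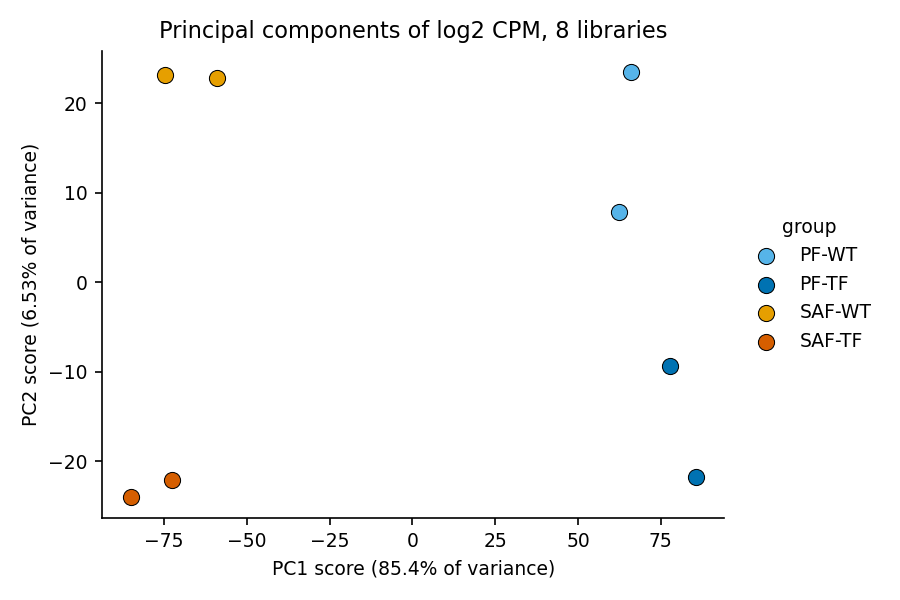
Scores of the 8 libraries on the first principal components of log2 CPM, with PC1 (85.4% of the variance) on the x axis, PC2 (6.53%) on the y axis and 1 point per library. PC1 parts PF from SAF, and PC2 parts TF from WT at each stage.

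In wild type follicles, transcripts of the oocyte were lower at the small antral than at the preantral stage, and transcripts of theca, stroma and the vessel wall were higher. The comparison asks which transcripts change in level as the follicle grows an antrum. CPM are relative to all reads of a whole follicle. Here and below, a change in its mix of cells cannot be told from a change within cells. Of 46 measured oocyte genes, 0 rose and 38 fell, or 1 and 39 adjusted over the list alone, with a median log2 fold change of -4.01 (camera adjusted p = 6.81e-18, adjusted p = 0.484 with an estimated correlation). Bmp15 and Gdf9 encode growth factors that the oocyte secretes. Bmp15 went from 697 ± 143 to 19.8 ± 4.49 CPM (log2 fold change -5.14 ± 0.37, adjusted p = 4.58e-05). Gdf9 went from 972 ± 427 to 53.3 ± 40.3 CPM (-4.19 ± 0.53, adjusted p = 4.25e-04). Mos, the kinase that holds the egg in meiotic arrest, fell as well (-5.71 ± 0.39, adjusted p = 4.58e-05), as did the oocyte transcription factor Nobox (-4.18 ± 0.62, adjusted p = 0.00103). The zona protein gene Zp3 (-1.21 ± 0.83, adjusted p = 0.284), the transcription factor gene Figla (0.41 ± 0.52, adjusted p = 0.570) and the germ cell helicase gene Ddx4 (-1.08 ± 0.50, adjusted p = 0.123) did not pass. Bmp15 lies on chromosome X at 6314054 to 6320724 and Gdf9 on chromosome 11 at 53430774 to 53437904 of GRCm38.

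Of 22 stroma and fibroblast genes, 18 rose and 1 fell, or 19 and 1 adjusted over the list alone, with a median of 2.71 (camera adjusted p = 7.50e-12, adjusted p = 0.484 with an estimated correlation). Mfap5, a microfibril protein, rose from 11.3 ± 4.49 to 677 ± 132 CPM (log2 fold change 5.91 ± 0.34, adjusted p = 4.50e-05). The matrix proteoglycan Dcn rose too (3.32 ± 0.41, adjusted p = 3.85e-04). Among 18 theca and interstitial genes, 12 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.12e-06, adjusted p = 0.484 with an estimated correlation). Among them were the androgen enzyme gene Cyp17a1 (2.37 ± 0.45, adjusted p = 0.00359), the luteinizing hormone receptor gene Lhcgr (3.81 ± 0.53, adjusted p = 6.99e-04) and the hedgehog-binding gene Hhip (4.69 ± 0.59, adjusted p = 4.25e-04). Of 14 smooth muscle and pericyte genes 10 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.35e-07, adjusted p = 0.484 with an estimated correlation). Of 17 endothelial genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 5.99e-04, adjusted p = 0.484 with an estimated correlation). The endothelial sialomucin gene Emcn was one (4.85 ± 0.51, adjusted p = 1.74e-04). Star and Cyp11a1, which bring cholesterol into mitochondria and cleave its side chain, rose by 2.31 ± 0.40 (adjusted p = 0.00228) and 1.78 ± 0.51 (adjusted p = 0.0227) on the log2 scale. Of 17 luteal genes 10 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00267, adjusted p = 0.484 with an estimated correlation).

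Cell division genes were lower in SAF-WT, and ribosomal protein genes higher. Of 34 granulosa genes, 0 rose and 9 fell, or 0 and 9 adjusted over the list alone (camera adjusted p = 0.189, adjusted p = 0.679 with an estimated correlation, no call). The inhibin subunit gene Inha (-2.60 ± 0.32, adjusted p = 3.51e-04), anti-Mullerian hormone gene Amh (-4.60 ± 0.95, adjusted p = 0.00529), aromatase gene Cyp19a1 (-3.57 ± 0.72, adjusted p = 0.00464) and follicle-stimulating hormone receptor gene Fshr (-1.26 ± 0.40, adjusted p = 0.0355) were lower in SAF-WT. Among 40 cell cycle genes, 1 rose and 22 fell, or 1 and 23 adjusted over the list alone (camera adjusted p = 9.03e-06, adjusted p = 0.484 with an estimated correlation). The mitotic checkpoint gene Bub1b stood at -2.85 ± 0.24 and the kinase gene Aurka at -2.40 ± 0.24. Of 25 DNA methylation and chromatin genes 1 rose and 12 fell, or 2 and 13 adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.484 with an estimated correlation). Dnmt3l, Tet3 and Dnmt1 changed by -3.89, -2.15 and -2.95 on the log2 scale. Of 48 cytosolic ribosomal proteins 40 rose and 0 fell, or 43 and 0 adjusted over the list alone (camera adjusted p = 4.58e-19, adjusted p = 0.379 with an estimated correlation). Of 40 oxidative phosphorylation genes 24 rose and 0 fell, or 24 and 1 adjusted over the list alone (camera adjusted p = 1.57e-09, adjusted p = 0.379 with an estimated correlation).

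By size alone, the genes that rose most in SAF-WT also held the surface antigen gene Ly6k (1 count in PF-WT, ratio 227.7 with a counting interval of 40.5 to 9033), Ctla2a (5.70 ± 0.41), Ms4a4d (5.51 ± 0.48), Ecscr (5.36 ± 0.57), the neurotrophin gene Bdnf (5.36 ± 0.99) and the stromal genes Ogn (5.26 ± 0.66) and Aspn (5.26 ± 0.75). Magea10 was at least 76.4-fold lower in SAF-WT than in PF-WT, Olfr288 at least 38.0-fold, Ighg3 at least 37.5-fold, Unc80 at least 37.3-fold, Igfals at least 32.4-fold, Tmem74 at least 29.1-fold and Gsdmc4 at least 28.6-fold, each with no count in SAF-WT. Fcgbp had 2 counts in SAF-WT, a ratio of 374.0 (counting interval 103.2 to 3095).

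In all, 6294 of 17925 genes passed in wild type, 2268 higher and 4026 lower in SAF, with a median log2 fold change over all genes of -0.20. The share of higher genes, 36.0%, depended on scaling and was 53.6% with the authors' scale factors and 52.4% with the correction for GC content and transcript length, added after seeing the data, as the median moved to 0.14 and 0.16. In the authors' deposited table, genes that passed numbered 7696, 4586 higher and 3110 lower, and 4990 were called by both tests, all in the same direction. Without SAF-WT replicate 1, 3119 genes passed. In that setting there were 20 cytosolic ribosomal proteins and 13 oxidative phosphorylation genes higher. Lower were 10 cell cycle, 3 granulosa and 7 DNA methylation and chromatin genes, and 4 luteal cells genes were higher. The cell cycle count was 13 without SAF-WT replicate 2 and 14 with the GC and length correction. Luteal cells counted 6 without SAF-WT replicate 2 and 5 without PF-WT replicate 2. The endothelium count was 5 without SAF-WT replicate 2 and 4 without PF-WT replicate 2.

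In follicles from transplanted FGSCs, the oocyte transcripts were again lower at the small antral stage, and steroidogenic, luteal, macrophage and stroma transcripts were higher. Of 46 oocyte genes 0 rose and 45 fell, or 0 and 45 adjusted over the list alone, with a median of -5.60 (camera adjusted p = 2.99e-22, adjusted p = 0.484 with an estimated correlation). Gdf9 went from 2638 ± 446 to 27.4 ± 0.694 CPM (log2 fold change -6.59 ± 0.59, adjusted p = 4.87e-05). Bmp15 went from 1206 ± 362 to 16.3 ± 6.01 CPM (-6.21 ± 0.39, adjusted p = 1.78e-05), and Ddx4 from 165 ± 36.8 to 3.11 ± 0.890 CPM (-5.72 ± 0.60, adjusted p = 1.03e-04). Zp3 (-5.30 ± 0.98, adjusted p = 0.00218), Figla (-3.87 ± 0.59, adjusted p = 7.86e-04), Nobox (-6.31 ± 0.69, adjusted p = 1.28e-04), Dppa3 (-4.38 ± 0.53, adjusted p = 2.19e-04) and Amh (-2.85 ± 0.80, adjusted p = 0.0174) fell too.

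Of 17 luteal genes 16 rose and 0 fell, or 16 and 0 adjusted over the list alone, with a median of 4.37 (camera adjusted p = 1.17e-11, adjusted p = 0.420 with an estimated correlation). Akr1c18, the enzyme that inactivates progesterone, rose from 6.37 ± 0.0773 to 10937 ± 579 CPM (log2 fold change 10.74 ± 0.24, adjusted p = 3.15e-08). Each of the 6 libraries outside SAF-TF held 54 to 64 counts of it. The Wnt antagonist gene Sfrp4 rose from 0.462 ± 0.340 to 1002 ± 413 CPM (11.01 ± 0.57, adjusted p = 1.50e-05). Among 19 steroidogenesis genes 13 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.95e-06, adjusted p = 0.484 with an estimated correlation). Star stood at 8.04 ± 0.49, Cyp11a1 at 9.03 ± 0.70 and its electron donor Fdx1 at 5.35 ± 0.32. Lhcgr rose by 7.35 ± 0.62. Aromatase (Cyp19a1, 0.44 ± 0.66, adjusted p = 0.620), Cyp17a1 (0.48 ± 0.50, adjusted p = 0.463) and Fshr (0.04 ± 0.39, adjusted p = 0.942) did not pass.

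Markers of other ovarian cells moved with the stage. Of 24 macrophage and immune genes 21 rose and 0 fell, or 23 and 0 adjusted over the list alone (camera adjusted p = 6.74e-10, adjusted p = 0.484 with an estimated correlation). Examples are the class II antigen gene H2-Ab1 (5.28 ± 0.50, adjusted p = 6.38e-05) and the macrophage gene Emr1 (5.61 ± 0.62, adjusted p = 1.36e-04). Of 22 stroma genes 19 rose and 0 fell, or 20 and 0 adjusted over the list alone (camera adjusted p = 1.17e-09, adjusted p = 0.484 with an estimated correlation). Of 14 smooth muscle genes 13 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.06e-06, adjusted p = 0.484 with an estimated correlation). Of 18 theca genes 11 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 2.85e-04, adjusted p = 0.484 with an estimated correlation). Of 17 endothelial genes 10 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 3.43e-04, adjusted p = 0.488 with an estimated correlation). Of 14 ovarian surface epithelium genes 11 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00187, adjusted p = 0.547 with an estimated correlation). Among 40 cell cycle genes 1 rose and 32 fell, or 1 and 33 adjusted over the list alone (camera adjusted p = 5.45e-10, adjusted p = 0.484 with an estimated correlation). Of 48 cytosolic ribosomal proteins 39 rose and 1 fell, or 42 and 1 adjusted over the list alone (camera adjusted p = 6.06e-11, adjusted p = 0.484 with an estimated correlation). Of 40 oxidative phosphorylation genes 30 rose and 0 fell, or 31 and 0 adjusted over the list alone (camera adjusted p = 1.54e-10, adjusted p = 0.379 with an estimated correlation).

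The largest increases in TF also held the secreted phosphoprotein gene Spp1 (1 count in PF-TF, ratio 3766 with a counting interval of 675.6 to 148808), and Onecut2 (1 count in PF-TF, ratio 2103, interval 377.0 to 83093). Of the others, 4 had no count in PF-TF: Hoxd10 (at least 125.1-fold), Wisp2 (at least 103.1-fold), Il33 (at least 81.7-fold) and Saa2 (at least 77.5-fold). With no count in SAF-TF, Oas1f was at least 68.9-fold lower, Vmn2r51 at least 48.7-fold, Pla2g4d at least 43.2-fold and Tmem74 at least 31.3-fold. Rln3 (ratio 965.3, interval 172.9 to 38164), Kcnk18 (457.6, interval 81.7 to 18111) and Gpr149 (435.9, interval 77.8 to 17252) had 1 count in SAF-TF. Pabpn1l stood at -8.50 ± 0.49.

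In all, 7744 genes passed in TF, 3261 higher and 4483 lower, with a median log2 fold change of -0.08. The share of higher genes was 42.1%, and 55.8% with the authors' scale factors and 50.3% with the later GC and length correction, as the median moved to 0.27 and 0.10. In the authors' deposited table, genes that passed numbered 9004, 5300 higher and 3704 lower, and 6404 were called by both tests, all in the same direction. The count of all genes stayed within 1.5 times when any library was left out. The higher cytosolic ribosomal proteins numbered 15 without PF-TF replicate 1 and 18 without SAF-TF replicate 2, and endothelium counted 6 without SAF-TF replicate 1.

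The stage effects of TF and WT, which share no library, went the same way in most genes. Across the 17925 genes their log2 fold changes correlated at Pearson's r = 0.75 and Spearman's rho = 0.76. In both sources 1606 genes were higher, against 412.6 for independent calls, and 3149 were lower, against 1007. Another 47 were called in opposite directions. A direct test of the difference, the stage by source interaction, passed for 162 genes, of which 118 rose more (or fell less) with stage in TF and 44 the reverse. Without SAF-WT replicate 1 the balance turned, with 39 that rose more and 51 the reverse.

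**Figure D2:**
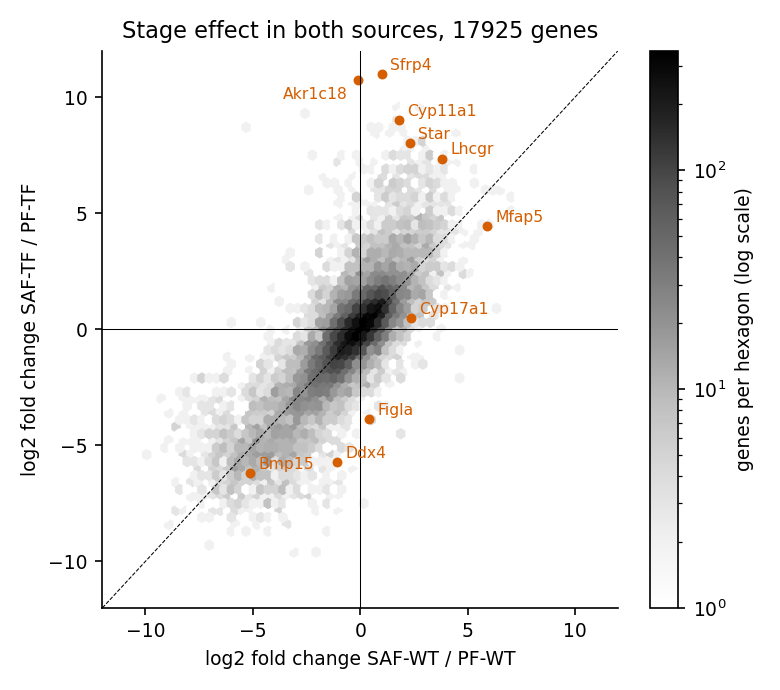
Log2 fold change of SAF over PF in wild type (x axis) against that in follicles from transplanted FGSCs (y axis), with the number of genes per hexagon in grey on a log scale, 10 named genes as points and the line of equal change dashed. Akr1c18 sits at -0.11 in WT and 10.74 in TF, and Ddx4 at -1.08 and -5.72.

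Steroid and luteal genes were among those whose stage effect differed. In this test a gene rose or fell where its change with stage was more positive or more negative in TF than in WT. Of 17 luteal genes 8 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 3.55 (camera adjusted p = 2.90e-16, adjusted p = 0.379 with an estimated correlation). Of 19 steroidogenesis genes 5 rose and 0 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.97e-10, adjusted p = 0.379 with an estimated correlation). Akr1c18 (10.85 ± 0.29, adjusted p = 1.36e-07), Sfrp4 (10.01 ± 0.87, adjusted p = 0.00170), Star (5.73 ± 0.58, adjusted p = 0.00429), Cyp11a1 (7.24 ± 0.78, adjusted p = 0.00488) and the choline enzyme gene Bhmt (9.50 ± 1.10, adjusted p = 0.00680) rose more with stage in TF. Of 24 macrophage and immune genes 5 rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 9.05e-15, adjusted p = 0.484 with an estimated correlation). H2-Ab1 stood at 5.77 ± 0.66. Among oocyte genes 0 of 46 rose and 2 fell, or 0 and 17 adjusted over the list alone (camera adjusted p = 1.70e-14, adjusted p = 0.484 with an estimated correlation). Those past the threshold over all genes were Ddx4 (-4.64 ± 0.75, adjusted p = 0.0269) and Figla (-4.28 ± 0.78, adjusted p = 0.0393). Gdf9 (-2.40 ± 0.67, adjusted p = 0.134) and Zp3 (-4.09 ± 1.20, adjusted p = 0.146) did not pass. Purine enzyme gene Xdh (-4.11 ± 0.61), Zdbf2 (-4.25 ± 0.74), Bcmo1 (-4.32 ± 0.77), Fmr1nb (-4.68 ± 0.89), Wfdc3 (-3.83 ± 0.63) and Mir686 (-4.06 ± 0.72) fell more with stage in TF. Cplx1, Igkc, Adcyap1 and Ccl9 also passed, but had no count in PF-TF, so their fitted values are no bound. They reached 16.2, 20.1, 14.8 and 17.8 CPM in SAF-TF. The count of 162 fell to 30, 97, 59, 90 and 23 without SAF-TF replicate 1, SAF-TF replicate 2, PF-TF replicate 1, SAF-WT replicate 1 and SAF-WT replicate 2. It rose to 291 without PF-WT replicate 2 and was 74 with the replicate number as a block. Luteal cells then counted 4 (without SAF-TF replicate 1), 5 (PF-TF replicate 1 or SAF-WT replicate 1) and 3 (SAF-WT replicate 2). Steroidogenesis counted 3 without SAF-WT replicate 2 and 8 without SAF-TF replicate 2. Macrophages and immune cells counted between 1 (without SAF-TF replicate 1 or either SAF-WT library) and 12 (without PF-WT replicate 2). The oocyte count was 12 without SAF-WT replicate 1 and 0 without either SAF-TF library, PF-TF replicate 1 or SAF-WT replicate 2.

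Small antral follicles of the 2 sources differed in luteal and steroidogenic transcripts, which were higher in SAF-TF. The comparison asks whether follicles from transplanted FGSCs differ from wild type ones at this stage. Genes of the mitochondrial genome held 3.85% and 2.96% of counts in SAF-TF against 1.70% and 2.06% in SAF-WT. The 10 genes with most counts held 10.3% and 9.34% against 6.27% and 6.30%. Whether RNA quality differed between these libraries was not tested. Of 17 luteal genes 15 rose and 1 fell, or 16 and 1 adjusted over the list alone, with a median log2 fold change of 2.92 (camera adjusted p = 4.94e-17, adjusted p = 0.379 with an estimated correlation). Akr1c18 stood at 10937 ± 579 CPM in SAF-TF and 6.53 ± 0.479 in SAF-WT (log2 fold change 10.71 ± 0.24, adjusted p = 3.24e-08). Sfrp4 stood at 1002 ± 413 and 2.50 ± 0.190 CPM (8.64 ± 0.49, adjusted p = 7.48e-05). The prostaglandin F receptor gene Ptgfr (6.55 ± 0.42, adjusted p = 1.11e-04) was higher as well. Onecut2 had 1 count in SAF-WT and a ratio of 1899 (counting interval 340.5 to 75054). Among 19 steroidogenesis genes 11 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 1.90 (camera adjusted p = 7.57e-11, adjusted p = 0.379 with an estimated correlation). Star went from 27.1 ± 7.21 CPM in SAF-WT to 1077 ± 299 in SAF-TF (5.31 ± 0.42, adjusted p = 2.88e-04). Cyp11a1 went from 166 ± 3.37 to 5240.4 ± 3673 CPM (4.98 ± 0.58, adjusted p = 0.00274). Lhcgr (2.31 ± 0.47, adjusted p = 0.0185) and, near the threshold, Fshr (1.46 ± 0.40, adjusted p = 0.0489) were higher. Akr1c18 lies on chromosome 13 at 4132615 to 4150646, Star on chromosome 8 at 25808474 to 25815982 and Cyp11a1 on chromosome 9 at 57998024 to 58027031 of GRCm38.

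Theca genes went both ways. Of 18 theca and interstitial genes 5 rose and 5 fell, or 5 and 8 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 0.272, adjusted p = 0.656 with an estimated correlation, no call). Cyp17a1 was lower in SAF-TF at 3.50 ± 0.962 against 44.3 ± 4.02 CPM (-3.66 ± 0.49, adjusted p = 0.00447). So were the theca hormone gene Insl3 (-4.47 ± 0.91, adjusted p = 0.0187), Hhip (-3.99 ± 0.57, adjusted p = 0.00557) and the hedgehog receptor gene Ptch1 (-2.64 ± 0.34, adjusted p = 0.00402). Of 22 stroma genes 1 rose and 3 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 7.06e-04, adjusted p = 0.606 with an estimated correlation). Mfap5 stood at -3.62 ± 0.30. Of 24 macrophage and immune genes 9 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median of 1.99 (camera adjusted p = 3.28e-10, adjusted p = 0.484 with an estimated correlation). The class II genes H2-Ab1 (3.68 ± 0.45, adjusted p = 0.00352) and H2-Aa (4.20 ± 0.56, adjusted p = 0.00442) were among them. Among granulosa genes 3 of 34 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0239, adjusted p = 0.600 with an estimated correlation). Inha stood at 2.26 ± 0.31 and Wnt4 at 4.31 ± 0.86.

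Ribosomal protein and cell cycle genes were lower in SAF-TF. Of 48 cytosolic ribosomal proteins 0 rose and 38 fell, or 0 and 44 adjusted over the list alone, with a median of -0.99 (camera adjusted p = 1.52e-30, adjusted p = 0.379 with an estimated correlation). Genes whose symbol starts with Rpl or Rps and a digit, a set not limited to these 48, were also counted. They held 3.37% and 3.93% of all counts in SAF-TF against 6.85% and 6.65% in SAF-WT. Rps18 had the smallest p of the 48 (-2.08 ± 0.20, adjusted p = 0.00104). Counts of its pseudogene Gm10260 were at 237.0 and 329.1 CPM in SAF-TF and at 18.6 and 14.8 CPM in SAF-WT, and the sum of the pair stood at -1.42 ± 0.20 (adjusted p = 0.00550). Among 40 cell cycle genes 0 rose and 16 fell, or 1 and 22 adjusted over the list alone, with a median of -0.82 (camera adjusted p = 5.95e-09, adjusted p = 0.484 with an estimated correlation). The survivin gene Birc5 (-1.75 ± 0.24) and the cyclin gene Ccna2 (-1.40 ± 0.22) fell. The cell cycle inhibitor gene Cdkn1a, counted with the p53 genes, rose (4.15 ± 0.42, adjusted p = 0.00124). Of 40 oxidative phosphorylation genes 0 rose and 10 fell, or 4 and 19 adjusted over the list alone (camera adjusted p = 5.25e-04, adjusted p = 0.484 with an estimated correlation). Of 46 oocyte genes 0 rose and 7 fell, or 0 and 12 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 4.40e-04, adjusted p = 0.652 with an estimated correlation). Figla (-3.22 ± 0.58, adjusted p = 0.0130) and Dppa3 (-2.83 ± 0.50, adjusted p = 0.0115) fell. Gdf9 (-0.96 ± 0.48, adjusted p = 0.222) and Bmp15 (-0.28 ± 0.32, adjusted p = 0.611) did not pass.

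By size, SAF-TF was also higher in Ssu2 (2 counts in SAF-WT, ratio 757.1, interval 209.2 to 6257), Adcyap1 (2 counts, ratio 127.5, interval 35.0 to 1059), Bhmt (7.38 ± 0.61) and the serum amyloid gene Saa2 (6.63 ± 0.66). It was lower in St6gal2 (-5.12 ± 0.66), Cst9 (-4.75 ± 1.11), Dleu7 (-4.72 ± 0.57), Pi15 (-4.63 ± 0.53), Xdh (-4.50 ± 0.48), Mir686 (-4.44 ± 0.57) and Zfp33b (-4.23 ± 0.48). In all, 1785 genes passed, 827 higher and 958 lower. The share of higher genes, 46.3%, was 68.1% and 59.3% without SAF-TF replicates 1 and 2, 59.0% and 59.3% without PF-TF replicates 1 and 2 and 54.5% without PF-WT replicate 1, and 36.1% (69 higher and 122 lower) without SAF-WT replicate 1. There were 116, 982, 191 and 200 without SAF-TF replicate 1, SAF-TF replicate 2, SAF-WT replicate 1 and SAF-WT replicate 2, and 1069 with the replicate number as a block. In that order of libraries the counts were 9, 14, 8 and 7 higher luteal cells genes, 6, 11, 6 and 6 higher steroidogenesis genes and 3, 4, 2 and 3 higher macrophages and immune cells genes. For the lower genes they were 2, 19, 2 and 4 lower cytosolic ribosomal proteins, 0, 17, 1 and 3 lower cell cycle genes, 0, 1, 9 and 0 lower oocyte genes and 0, 4, 1 and 1 lower oxidative phosphorylation genes. The oocyte median was -1.56 without SAF-TF replicate 1 and -0.05 without SAF-WT replicate 2. Theca counted 1, 4, 1 and 1 higher and 1, 5, 3 and 3 lower, granulosa 1, 3, 0 and 1 higher and stroma 1, 1, 1 and 2 lower. Without PF-WT replicate 1 macrophages and immune cells counted 14, and the oocyte count was 4 without either PF-TF library and 11 without either PF-WT library, while granulosa counted 6 and 8. Oxidative phosphorylation counted 5 without either PF-TF library and 4 with the GC and length correction, and 4 rose without PF-WT replicate 1.

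**Figure D3:**
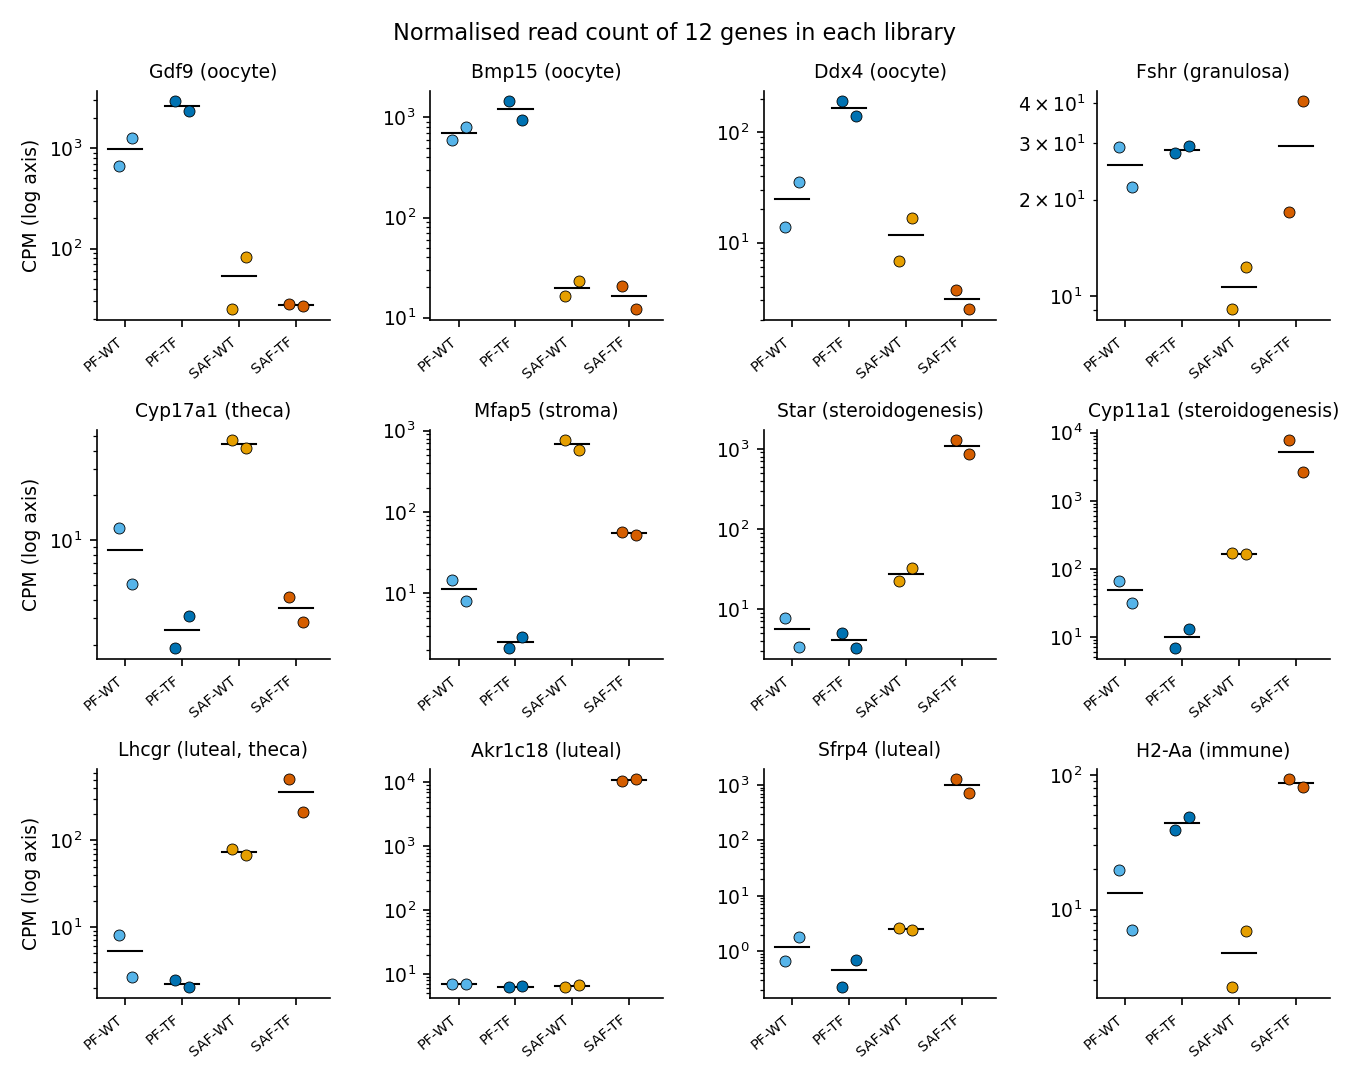
Normalised read counts in CPM (log axis) of 12 genes in the 8 libraries, with 1 point per library and a line at the mean of each group. Akr1c18 stands at 10937 CPM in SAF-TF and at 6.20 to 7.09 CPM in the 6 other libraries, and Cyp17a1 at 44.3 CPM in SAF-WT and 3.50 in SAF-TF.

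Few single genes passed between preantral follicles of the 2 sources. In simulated data, where more genes were called, this test recovered 0% of 2-fold and 38% of 4-fold changes. PF-TF was higher in Pou5f1, a transcription factor of pluripotent cells and oocytes, at 122 ± 18.5 against 11.7 ± 6.83 CPM (log2 fold change 3.38 ± 0.54, adjusted p = 0.0499). Lrrc31 was at 28.2 ± 9.8 against 0.353 ± 0.128 CPM (6.24 ± 0.87, adjusted p = 0.0416). Crym (3.07 ± 0.48), Abcd4 (2.90 ± 0.46), the class I gene H2-T22 (2.47 ± 0.27), Gpx6 (2.01 ± 0.31) and the growth factor gene Mdk (1.35 ± 0.20) were higher too. PF-TF was lower in Car3, with 2 counts and a ratio of PF-WT to PF-TF of 455.8 (counting interval 125.8 to 3770). It was lower in Spp1, with 1 count and a ratio of 199.9 (interval 35.4 to 7941). The others were the fatty acid carrier gene Fabp4 (-6.33 ± 0.85), the caveolin gene Cav2 (-3.84 ± 0.46), Ctgf (-3.06 ± 0.42), Arrdc3 (-2.96 ± 0.34), Fkbp11 (-2.63 ± 0.34) and Tmem100 (-2.35 ± 0.26).

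Among the lists, oocyte genes had a median of 0.68 in PF-TF over PF-WT, and 0 of 46 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 1.17e-08, adjusted p = 0.543 with an estimated correlation). Ddx4 was at 2.74 ± 0.51, adjusted p = 0.0580, Gdf9 at 1.44 ± 0.47, adjusted p = 0.131 and Zp3 had an adjusted p = 0.428. Markers of cells around the follicle had negative medians: -1.98 for 22 stroma genes, of which 0 rose and 1 fell, or 0 and 14 adjusted over the list alone (camera adjusted p = 4.05e-06, adjusted p = 0.530 with an estimated correlation). The median was -2.00 for 14 smooth muscle genes, of which 0 rose and 0 fell, or 0 and 7 adjusted over the list alone (camera adjusted p = 8.73e-04, adjusted p = 0.547 with an estimated correlation). Of 24 macrophage and immune genes 0 rose and 0 fell, or 1 and 16 adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.635 with an estimated correlation). Erythroid genes had a median of -4.36, and 0 of 6 rose and 0 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.484 with an estimated correlation). Theca genes had a median of -1.21, and 0 of 18 rose and 0 fell, or 1 and 10 adjusted over the list alone (camera adjusted p = 0.0108, adjusted p = 0.484 with an estimated correlation). Of 48 cytosolic ribosomal proteins 0 rose and 1 fell, or 0 and 46 adjusted over the list alone, with a median of -0.84 (camera adjusted p = 2.99e-29, adjusted p = 0.379 with an estimated correlation). The member that passed was Rps18 (-1.82 ± 0.20, adjusted p = 0.0212), but it did not pass when fitted as a sum with its pseudogene Gm10260 (-1.12 ± 0.20, adjusted p = 0.0583), a later test. Counts assigned to the pseudogene were higher in PF-TF, at 145.4 and 149.6 against 5.91 and 5.99 CPM. Part of the fold of Rps18 alone thus depends on how reads were assigned within the pair. The counts of the pair were divided unlike between the sources. Rps18 alone was at 214.5 and 242.2 CPM in PF-TF against 888.3 and 728.7 CPM in PF-WT. It was at 432.9 and 516.5 CPM in SAF-TF against 2130 and 1883 CPM in SAF-WT, where the pseudogene was again higher in TF. What divided them so was not tested. Genes whose symbol starts with Rpl or Rps and a digit, not only the 48 listed, held 2.10% and 2.40% of all counts in PF-TF. They held 4.07% and 3.55% in PF-WT. Oxidative phosphorylation genes had a median of -0.61, and 0 of 40 rose and 0 fell, or 0 and 23 adjusted over the list alone (camera adjusted p = 1.22e-10, adjusted p = 0.379 with an estimated correlation).

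In all, 39 genes passed, 12 higher and 27 lower in PF-TF, beside 3719 of 17925 at an unadjusted p under 0.05. Without any difference, a share near 0.05 would be expected there. The few calls thus do not show that the follicles were alike. The DESeq2 Wald test called 1322 and voom with quality weights 8. The count was 1 without PF-TF replicate 1 or SAF-WT replicate 1, 16 and 11 without SAF-TF replicates 1 and 2. It was 8 without SAF-WT replicate 2, 6 without PF-WT replicate 1 or with the replicate number as a block, and 865 without PF-WT replicate 2. In that last setting 27 cytosolic ribosomal proteins, 11 macrophages and immune cells genes and 8 stroma genes fell, as did 11 oxidative phosphorylation, 7 smooth muscle and 5 theca genes, and 7 granulosa genes rose. The fit of only the 4 libraries compared had 10 genes higher and 9 lower. The median of stroma lay between -2.83 (without PF-TF replicate 2) and -0.88 (without PF-WT replicate 1), and that of theca between -1.50 and -0.76 in the same settings. Smooth muscle went from -2.63 (without PF-WT replicate 2) to -0.87 (without PF-WT replicate 1). Erythroid genes went from -8.56, with 4 lower (without PF-TF replicate 2), to -3.39 (without PF-WT replicate 1). The oocyte median was 0.43 without PF-TF replicate 1 or PF-WT replicate 2 and 1.00 without PF-WT replicate 1, and that of oxidative phosphorylation was -0.29 with the GC and length correction. None of the 16 genes named as past the threshold passed without PF-TF replicate 1 or without SAF-WT replicate 1.

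Over both stages together, with stage as a covariate and 4 libraries on each side, ribosomal protein transcripts were lower in TF. Of 48 cytosolic ribosomal proteins 0 rose and 43 fell, or 0 and 48 adjusted over the list alone, with a median log2 fold change of -0.95 (camera adjusted p = 6.29e-36, adjusted p = 0.379 with an estimated correlation). The sign held under RLE factors and the GC and length correction. Of 40 oxidative phosphorylation genes 0 rose and 19 fell, or 1 and 24 adjusted over the list alone (camera adjusted p = 3.20e-08, adjusted p = 0.481 with an estimated correlation), though only 2 fell with that correction. Among 18 theca genes 2 rose and 7 fell, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.0965, adjusted p = 0.484 with an estimated correlation, no call). Hhip (-3.59 ± 0.51, adjusted p = 0.0102), Cyp17a1 (-2.75 ± 0.48, adjusted p = 0.0150) and Insl3 (-3.91 ± 0.71, adjusted p = 0.0172) fell. Ptgfr (5.72 ± 0.97, adjusted p = 0.0142) and Wnt6 (2.90 ± 0.50, adjusted p = 0.0148) rose. Of 22 stroma genes 0 rose and 7 fell, or 0 and 9 adjusted over the list alone (camera adjusted p = 1.23e-05, adjusted p = 0.484 with an estimated correlation). Mfap5 stood at -3.01 ± 0.34. Of 6 erythroid genes 0 rose and 4 fell, or 0 and 5 adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.484 with an estimated correlation). The globin gene Hba-a2 stood at -3.98 ± 0.84. Among 40 cell cycle genes 0 rose and 8 fell, or 0 and 14 adjusted over the list alone (camera adjusted p = 9.63e-05, adjusted p = 0.568 with an estimated correlation). Pou5f1 (2.86 ± 0.47, adjusted p = 0.0133), H2-Aa (2.92 ± 0.59, adjusted p = 0.0223), the lipid droplet gene Plin5 (4.79 ± 0.81), AA465934 (3.37 ± 0.71), Lrrn1 (3.01 ± 0.45) and the meiosis gene M1ap (2.77 ± 0.51) were higher in TF. Lmo3 (-6.29 ± 1.10), Slc26a3 (-4.46 ± 1.14), Pi15 (-4.27 ± 0.49), Dleu7 (-3.90 ± 0.66), the troponin gene Tnnt2 (-3.89 ± 0.49) and Rgs13 (-3.77 ± 0.88) were lower.

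In all, 1400 genes passed over both stages, 388 higher and 1012 lower in TF. The count was 310, 523, 123, 7, 382 and 525 without SAF-TF replicate 1, SAF-TF replicate 2, PF-TF replicate 1, SAF-WT replicate 1, SAF-WT replicate 2 and PF-WT replicate 1. It was 603 with the replicate number as a block and 472 with the GC and length correction. Cytosolic ribosomal proteins counted 5 lower without PF-TF replicate 1 and 1 without SAF-WT replicate 1. Leaving out any library but PF-WT replicate 2 gave 1 to 3 lower stroma genes, 0 to 5 cell cycle genes, 0 to 5 theca genes and 0 to 9 oxidative phosphorylation genes. The fewest were without SAF-WT replicate 1, and for oxidative phosphorylation also without PF-TF replicate 1. Erythroid genes counted 0 without either SAF-TF library, either SAF-WT library or PF-WT replicate 1, and 1 without PF-TF replicate 2 or with the GC and length correction. The source effects of the 2 stages, which share no library, correlated across genes at Pearson's r = 0.13 and Spearman's rho = 0.28. Of the calls, 5 genes were higher at both stages against 0.554 for independent calls, 10 were lower at both against 1.44, and 4 were opposite.

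**Figure D4:**
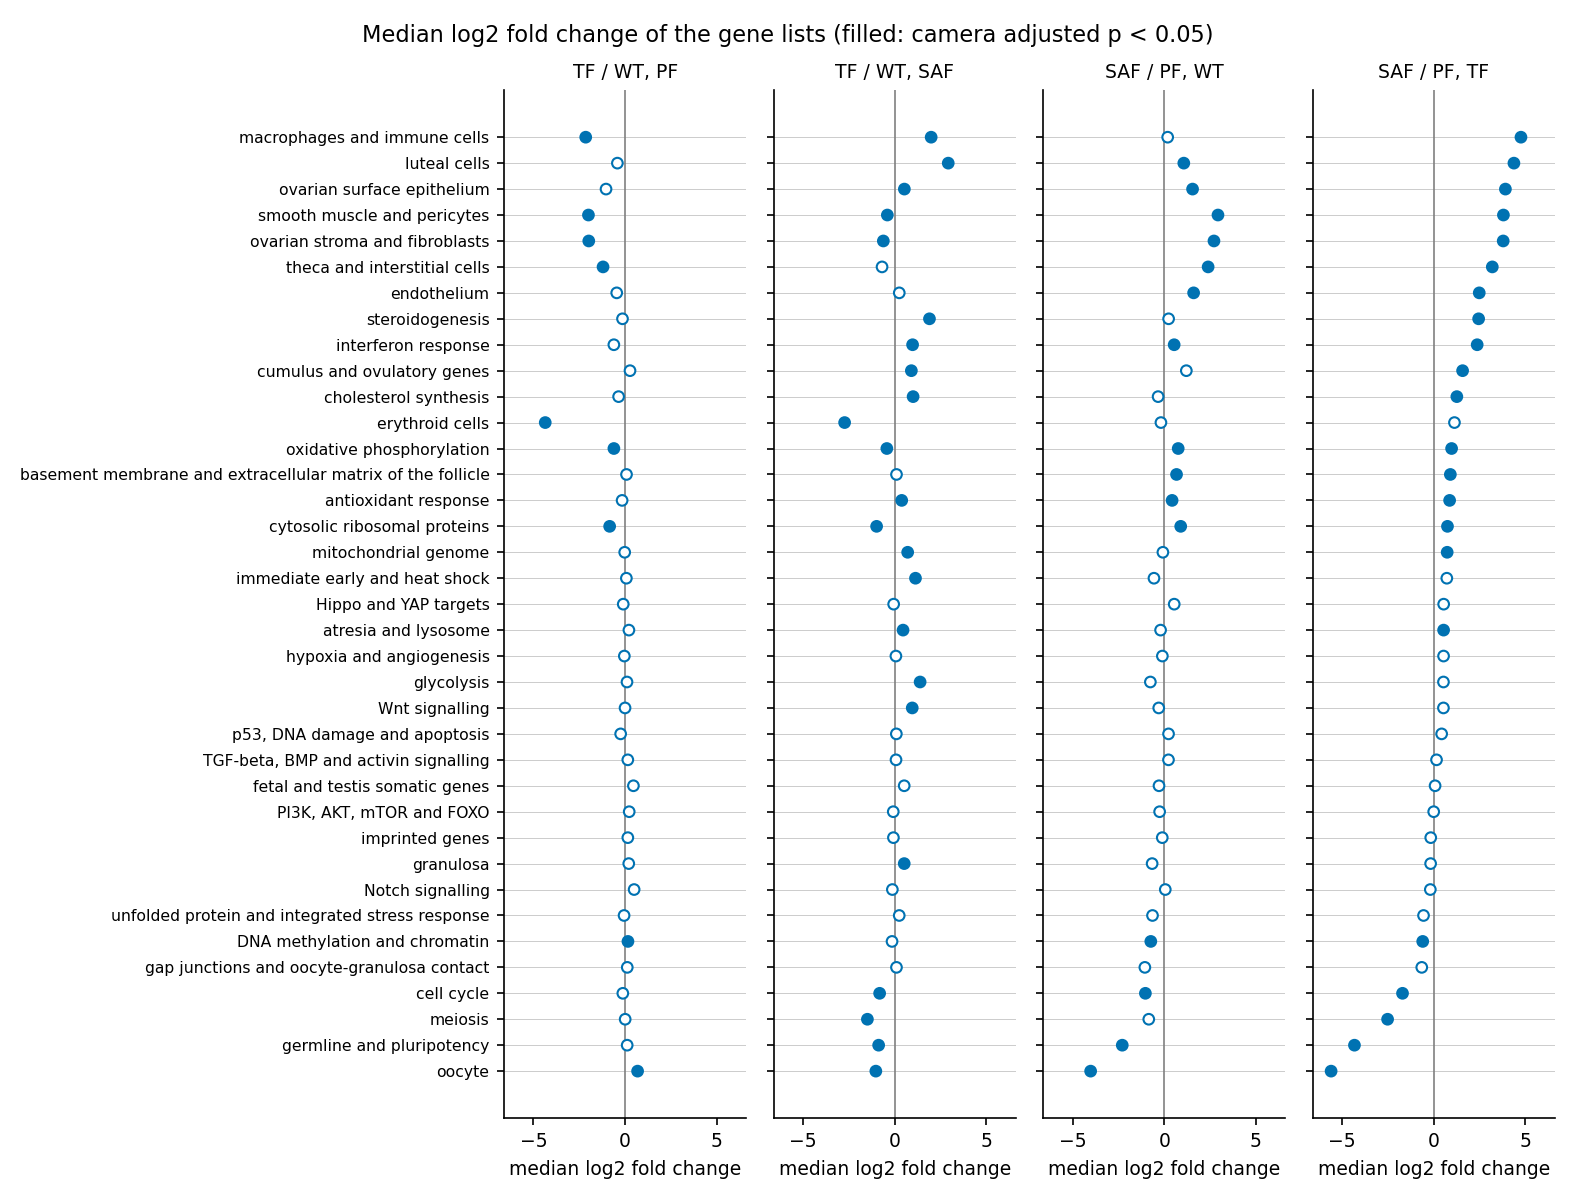
Median log2 fold change (x axis) of the 37 gene lists (y axis) in the 4 contrasts named above the panels, filled where camera at the preset correlation passed. The luteal list stands at 2.92 in SAF for TF over WT, and the oocyte list at -4.01 in WT and -5.60 in TF for SAF over PF.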

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

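The tests for theca cells and for luteal cells carried with the follicle were chosen only after the result was seen, and the correction for GC content and transcript length was added after seeing the data. A difference between groups drew attention to 162 genes whose stage effect differed between TF and WT. The largest fitted interactions on the log2 scale were 13.21 for Cplx1, 11.92 for Igkc, 11.77 for Adcyap1, 10.85 for Akr1c18, 10.12 for Ccl9, 10.01 for Sfrp4, 9.82 for Ly6d and 9.50 for Bhmt, and -4.68 for Fmr1nb, -4.64 for Ddx4, -4.32 for Bcmo1, -4.28 for Figla, -4.25 for Zdbf2, -4.11 for Xdh, -4.06 for Mir686 and -3.83 for Wfdc3. Star at 5.73 and Cyp11a1 at 7.24 differed too. Cplx1, Igkc, Adcyap1 and Ccl9 had no count in PF-TF, so their fitted values depend on the prior count and bound nothing.

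Data outside the tests held 132 genes listed only for TF and 141 listed only for WT, each with over 3 counts in a library. Their highest counts in a library were 48 (Vmn2r13, TF) and 95 (Gm13941, WT), and they summed to 2502 and 2688 counts. The other source has no entry for them, so no comparison was made.

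Luteal and steroidogenic genes were higher in SAF-TF than in SAF-WT, and a GC and length trend is argued against by the median of the luteal list, 3.03 on the log2 scale after that correction and 2.92 before. The 14 theca markers in neither the luteal nor the steroidogenesis list had a median of -0.82. Of these, 4 were lower (Insl3, Ptch1, Hhip, Enpep) and 3 higher (Mgarp, Wnt6, Aldh1a2). They did not rise as a set, as carried theca or interstitial cells would make them. Since they went both ways and steroidogenic genes were left out, such cells cannot be excluded. Luteal cells carried with the dissected follicle cannot be told apart from follicle cells that had taken on luteal transcripts, since the share of carried cells is not known and 11 of the 17 measured luteal genes are in another list, with 17 at 10 CPM or more in SAF-TF and 11 in SAF-WT. A fall of the granulosa list, which carried cells would bring, was not seen (median 0.52, with 4 of 34 genes also in the steroidogenesis list, and 0.46 for the 30 in neither that nor the luteal list), though its size would depend on that share, and the 6 luteal genes in no other list, which carried cells would raise, had a median of 2.95 with 5 higher and 1 lower. A difference between follicles from transplanted FGSCs and wild type follicles stays open as well and was not tested apart from the hosts, the dissection, or a hormone treatment or cycle stage, which are not given in the sources used here.

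The median of the cytosolic ribosomal protein list was negative in TF over WT at both stages. Of the 48 genes, 1 was lower past the threshold over all genes in PF and 38 in SAF. Camera with an estimated correlation called the list at neither stage (adjusted p = 0.379). A GC and length trend as the whole cause is argued against by medians of -0.61 in PF and -0.95 in SAF after that correction, with single TF and WT libraries apart by -0.67 to -0.56 and by -1.24 to -0.75 in the list's median. Reads counted to a pseudogene in place of its gene are argued against as the whole cause by sums over both. Counts summed over each gene and its pseudogenes (210 pseudogenes in 40 of 48 families) had medians of -0.83 in PF and -1.02 in SAF. The sums were lower for 48 of 48 at each stage, with library medians apart by -1.12 to -0.70 and by -0.95 to -0.78. Reads counted to neither, or belonging to copies that are not listed, are outside these sums, so their loss was not tested. Source effects of 16402 genes with a value tracked GC content, with Spearman's rho of 0.211 in PF and 0.358 in SAF and a median GC content of 53.5% in genes higher and 45.6% in genes lower in SAF-TF. A library batch that follows the source, which the labels do not give, could leave such a trend and stays open, as does a biological difference, both untested.

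Akr1c18 had 54 to 64 counts in each of the 6 libraries outside SAF-TF, 6.20 to 7.09 CPM, a 1.14-fold range. A constant share of reads from the other 6 Akr1c genes together is argued against, since their sum varied 3.26-fold over these libraries. Reads of a single one of them stay open, since each was not tested alone. Reads carried over between libraries may supply this level: it is 0.0616% of the SAF-TF count, and of 104 transcripts with 10 or more reads expected in PF-TF at that share, the lowest ratio of observed to expected was 0.809, for Sfrp4 with 9 reads against 11.1. Low true expression stays open, untested; under carry-over the fitted folds of Akr1c18 and Sfrp4 would be too small.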

How the results depend on the processing

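The GC and length correction, the protein-coding restriction, the authors' scale factors, the crossed block, the pseudocounts and the summed fit of Rps18 were chosen after seeing the data. No named gene that passed in the main or the alternative fit changed sign between them, and both correlations across genes stayed positive. The balance of higher and lower calls did turn in some settings. In the stage effect of WT it was 2268 higher and 4026 lower, and 3602 and 3113 with the authors' scale factors. Of the named genes that passed, 0 to 16 of 16 kept their call over the alternatives in the PF source effect, 21 to 38 of 38 in SAF, 35 to 39 of 39 and 32 to 33 of 33 in the stage effects of WT and TF, 5 to 19 of 19 in the interaction and 1 to 19 of 19 over both stages. Values outside 1.5 times the reported count follow, and except for fewer libraries or a looser threshold the cause was not tested. The PF source effect (39 genes) had 207 without a low-count filter, 1322 with DESeq2, 19 with only the 4 libraries compared, 8 with voom and quality weights, 245 with protein-coding genes, 1083 at a threshold of 0.1, and 1 to 865 with a library left out. The SAF source effect (1785) had 2849 with DESeq2, 3774 with only the 4 libraries, 4000 with voom, 1120 with the GC and length correction, 3388 at 0.1, and 116 to 2479 with a library left out. The stage effect had 3119 to 6563 genes in WT and 5231 to 8178 in TF with a library left out, and the other alternatives stayed within 1.5 times of 6294 and 7744. The interaction (162) had 810 with DESeq2, 106 with voom, 472 at 0.1, and 23 to 291 with a library left out. The source effect over both stages (1400) had 3131 with DESeq2, 3160 with voom, 472 with the GC and length correction, 2926 at 0.1, and 7 to 1953 with a library left out. A library left alone in its group was assumed to vary like the other groups. The correlation of the stage effects (0.75) moved to 0.67 without a filter, 0.82 with the filter at 10 CPM and 0.69 to 0.76 with a library left out, and that of the source effects (0.13) to 0.0592, 0.236, 0.0691 with the GC and length correction and 0.0765 to 0.16. Of the 102 list calls, camera with an estimated correlation gave 0 and fry 38, 36 of them shared. With pseudocounts of 2 and 5 in place of 0.5, camera called 104 and 98. The gene tests use counts, so no pseudocount was varied there.

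With the replicate number as a block, 6 genes passed in the PF source effect, 1069 in the SAF source effect, 74 in the interaction and 603 over both stages. The labels share only the replicate number between groups and state no pairing, and deviations of replicates correlated at -0.12 to 0.11 between groups. The block takes residual degrees of freedom, and whether a shared batch lies behind these numbers was not tested.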

Other observations

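Camera called the cholesterol synthesis, glycolysis and lysosome lists higher in SAF-TF than in SAF-WT. Of 22 cholesterol synthesis genes 5 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 7.65e-06, adjusted p = 0.484 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, stood at 1.48 ± 0.27, adjusted p = 0.0127. The count was 0 without SAF-TF replicate 1 or either SAF-WT library, 3 without SAF-TF replicate 2 and 8 without PF-WT replicate 1. Of 21 glycolysis genes 7 rose and 0 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 1.73e-04, adjusted p = 0.484 with an estimated correlation). Aldoa stood at 1.58 ± 0.27, adjusted p = 0.0101. In this list 0 rose without SAF-TF replicate 1 or either SAF-WT library and 3 with the GC and length correction. Of 17 lysosome and atresia genes 8 rose and 0 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 6.12e-04, adjusted p = 0.484 with an estimated correlation). The protease gene Ctsd stood at 1.94 ± 0.27, adjusted p = 0.00540. Without SAF-TF replicate 1, SAF-WT replicate 1 and SAF-WT replicate 2 the count was 1, 0 and 1, and it was 5 with that correction. Of 23 immediate early and heat shock genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00589, adjusted p = 0.484 with an estimated correlation). Dusp1 stood at 3.52 ± 0.55, adjusted p = 0.00789. The higher genes numbered 0 without SAF-TF replicate 1 or SAF-WT replicate 1, 1 without SAF-WT replicate 2 and 7 without either PF-WT library. Of 13 genes of the mitochondrial genome 1 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 1.81e-04, adjusted p = 0.566 with an estimated correlation). Between 0 (without SAF-TF replicate 1 or either SAF-WT library, or with the GC and length correction) and 6 (without either PF-WT library) of them rose. Of 13 cumulus and ovulatory genes 3 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0391, adjusted p = 0.547 with an estimated correlation), and 1 rose without SAF-WT replicate 1. A pseudocount of 5 ended the call of this list (camera adjusted p = 0.0665). Of 21 Wnt genes 3 rose and 0 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.535 with an estimated correlation), and 1 rose without SAF-TF replicate 1 or either SAF-WT library.

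With stage in TF, 17 of 26 interferon response genes rose and 1 fell, or 17 and 2 adjusted over the list alone (camera adjusted p = 1.64e-05, adjusted p = 0.484 with an estimated correlation). The immunoproteasome gene Psmb8 stood at 3.16 ± 0.29, adjusted p = 5.09e-05. Of 22 antioxidant genes 13 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.38e-05, adjusted p = 0.484 with an estimated correlation). The peroxidase gene Gpx1 stood at 2.52 ± 0.21, adjusted p = 3.27e-05. Among meiosis genes 0 of 17 rose and 10 fell, or 0 and 10 adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.484 with an estimated correlation). In the germline and pluripotency list 1 of 15 rose and 12 fell, or 1 and 12 adjusted over the list alone (camera adjusted p = 5.99e-04, adjusted p = 0.484 with an estimated correlation). Dazl stood at -4.92 ± 0.38, adjusted p = 2.38e-05.

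With stage in WT, of 27 basement membrane genes 9 rose and 2 fell, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00255, adjusted p = 0.484 with an estimated correlation). The nidogen gene Nid1 stood at 3.05 ± 0.40, adjusted p = 5.23e-04. Of 13 gap junction and oocyte contact genes 1 rose and 8 fell, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.106, adjusted p = 0.484 with an estimated correlation, no call). The connexin gene Gja4 stood at -4.65 ± 0.64, adjusted p = 6.49e-04. The count was 4 lower without SAF-WT replicate 1, and 5 without either PF-WT library or with the authors' scale factors. The lists that camera did not call in WT also held the unfolded protein response (adjusted p = 0.409), p53 and DNA damage (0.671), TGF-beta (0.439), Notch (0.883), Hippo (0.106), PI3K (0.857), hypoxia (0.384), imprinted (0.312) and fetal and testis somatic genes (0.883).

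Over the 6 contrasts, camera at the preset correlation called 102 of 222 tests and fry 38. Most fry calls were in the stage effects, with 10 of 37 lists in WT and 17 in TF. Fry called 2 lists in the PF source effect, 5 in the SAF source effect, 2 in the interaction and 2 over both stages. No camera call held with an estimated correlation (smallest adjusted p = 0.379). The 8 libraries can be split into 4 and 4 in 34 ways that could be fitted with stage as a covariate, the real one included. Of these 34 splits 1, the real one, gave as many as 1400 genes, and the highest of the others gave 2. Only 18 of them keep 2 libraries of each stage on each side, as the real one does, and 18 are too few for a share under 0.05. The other 16 hold unequal numbers of the stages on a side, and the split that follows stage could not be fitted. Without SAF-WT replicate 1 the real split gave 7 genes.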
